A study of Mus musculus with 16 samples.

How the data were processed

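Gene expression was measured by RNA sequencing in periodontal ligament of 9-week-old male C57BL/6J mice. The 16 libraries form 4 groups of 4: control, ligature, trauma, and ligature plus trauma. Per the labels' protocols, RNA was taken up in TRIzol, purified on a column kit and enriched for poly(A) RNA. The labels number the libraries within each group and do not say whether each library came from 1 mouse. The p-values therefore measure the spread between these libraries, which may be partly technical.

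The deposited table holds whole-number read counts per gene, not normalised, for 55359 genes in all 16 libraries. The submitters' processing notes name Trimmomatic 0.39, FastQC 0.11.9, HISAT2 2.2.1, StringTie 2.1.7 and DESeq2 1.32.0 with the mouse build GRCm39, without their roles or order. The tool that counted the reads, the annotation release, the strand setting and the read length are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene therefore cannot be told apart, and genes with a near-identical copy (Bglap and Bglap2, Saa1 and its neighbours) are uncertain one by one. The reference at hand is annotated on GRCm38 (GENCODE M21), so it served only for gene symbols and transcript lengths, and no coordinates are given. Symbols were found for 52083 of the gene identifiers, and genes without one held 0.205% of the counts.

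Total counts per library ranged from 58458102 to 77468584, and 32711 genes had any count. At this depth the spread between libraries, not counting error, sets the precision of the well-expressed genes named. No pair of libraries was alike enough to be 1 library listed more than once: the highest correlation of log2 CPM between any pair was 0.948.

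The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts, with trimmed-mean scaling and edgeR's expression filter (minimum count 10, by group). It kept 20953 genes. All 4 groups entered 1 fit with 12 residual degrees of freedom. The 5 pairwise contrasts were ligature against control, trauma against control, ligature plus trauma against control, against ligature and against trauma. The interaction was the effect of trauma with the ligature minus its effect without it, both on the log2 scale. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are given with the standard error (SE) and CPM (counts relative to the scaled library total) with the standard deviation (SD) over the 4 libraries of a group.

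Gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) in each contrast, adjusted over the 33 lists, and again with an estimated correlation and with fry, whose p tests whether a list's genes move on balance one way. The lists cover osteoclast, osteoclastogenic and resorption signals, inflammatory cytokines and chemokines, mature neutrophil, marrow granulocyte precursors, monocyte and macrophage, T and NK cell, B cell, plasma cell, antigen presentation, interferon-stimulated genes, osteoblast, osteocyte, periodontal ligament fibroblast, fibrillar collagen, matrix-degrading proteases and inhibitors, the YAP/TAZ and stretch response, immediate-early genes, hypoxia and glycolysis, Wnt targets and regulators, cell cycle, endothelial cells, oral epithelium, skeletal muscle, erythroid cells, odontoblast with pulp and enamel organ, Schwann cell and nerve, cartilage, adipocyte, salivary gland, mitochondrially encoded genes, nuclear oxidative phosphorylation and endoplasmic reticulum stress. A list score is the mean, over a list's members, of each gene's log2 CPM minus its mean over the 16 libraries.

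The groups, tests, gene lists and rule for named genes were fixed before the data were examined. The rule took, per comparison, up to 5 genes each way with the largest fold among those that passed, had a mean log2 CPM of at least 2 and ranges that did not overlap between the groups, without predicted genes and antigen-receptor segments. It added up to 4 members with the lowest p of each list described, and a panel of 10 genes (Tnfsf11, Tnfrsf11b, Acp5, Ctsk, Il1b, Il6, Postn, Bglap, Sost and Mmp13). Where no gene passed, the 3 with the lowest p were taken, together with the panel. Genes named from small counts of calls were chosen after their values were seen.

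Alternatives fixed in advance were DESeq2 1.42.0, its size factors within edgeR, no expression filter, a stricter filter (50 counts in 4 libraries), a fit of the compared groups only, the replicate number as a block, limma-voom with sample weights, and each library left out in turn. Added after seeing the data were 2 corrections for a trend with transcript length (the trend removed from each library by a spline with 5 degrees of freedom, and each library's slope on length as a covariate) and a fit of 13 libraries. The latter left out ligature 2, ligature plus trauma 2 and ligature plus trauma 3, whose counts were shifted to short transcripts. Lengths were found for 99.85% of the 11691 genes with a mean log2 CPM over 2.

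The test was tried on simulated counts with known changes, in a single draw per comparison. Changes were put only into genes above a minimum mean expression, 66 or 67 genes per size of change, so genes expressed less were not tried. Genes varied independently with edgeR's own estimate of the spread and without a shift to short transcripts. The shares below may therefore differ in the real counts. In ligature against control edgeR recovered 19.4% of genes changed 2-fold, 85.07% of those changed 4-fold and 92.42% of those changed 8-fold. The shares were 10.45%, 76.12% and 93.94% in trauma against control, and 16.42%, 83.58% and 98.48% in ligature plus trauma against control. Against ligature they were 23.88%, 80.6% and 95.45%, against trauma 7.463%, 70.15% and 90.91%, and in the interaction 2.985%, 31.34% and 87.88%. Among the calls, false ones made up 0.8264% to 3.676% with edgeR, 0.8% to 7.246% with voom and 24.34% to 33.14% with DESeq2. All simulations ran on 20953 genes. A trend with transcript length put into simulated counts of 12136 genes had a slope of -0.927 before its removal and 0.00124 after.

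No column of the table was left out. Isoforms, splicing and read-level quality were not analysed here, since the table holds 1 count per gene. Results for some single genes of the lists are not reported here, though these genes were counted in the lists.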

Results

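RNA sequencing was carried out on the periodontal ligament, the connective tissue that anchors a tooth root in its bony socket, of 9-week-old male C57BL/6J mice. The 16 libraries made up 4 groups with n = 4 each. Control mice were untreated. Ligature mice had a silk thread tied around an upper left molar, a standard way to bring on periodontitis. Trauma mice had resin built up on the biting surface of that molar, which overloads it (traumatic occlusion). The last group had both. The labels name the tissue as periodontal ligament, whereas the title of the series speaks of bone. Total counts per library were 68946101 to 77468584 in control, 61562188 to 69588348 in ligature, 58458102 to 77316734 in trauma and 59845593 to 72301909 in ligature plus trauma. Of 55359 genes, 20953 were tested. Adjusted p-values of genes are from edgeR's quasi-likelihood test and those of gene lists from camera, both with Benjamini-Hochberg adjustment.

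The libraries parted first by the ligature. The leading principal component of the 1000 most variable genes held 45.5% of the variance and the next 9.11%. Median correlations of log2 CPM were 0.924 within groups, 0.922 between groups of the same ligature status and 0.895 between groups of differing status. Skeletal muscle genes varied with the sample taken: their list score, in log2 units around the mean of all libraries, reached 3.06 in control 3, 4.94 in ligature 2 and 2.94 in ligature 3, and lay between -2.29 and -0.818 in the 4 trauma libraries. Oral epithelium genes scored 2.11, 2.79, 0.451 and -1.26 in controls 1 to 4, 0.569 to 3.63 in trauma and -2.41 to -0.33 in the 8 libraries with a ligature. In ligature 2 and in ligature plus trauma 2 and 3 the counts were shifted to short transcripts. Across genes, which are not independent replicates, their rank correlation of expression with transcript length was -0.605, -0.546 and -0.538, against -0.207 to 0.499 in the other 13.

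**Figure D1:**
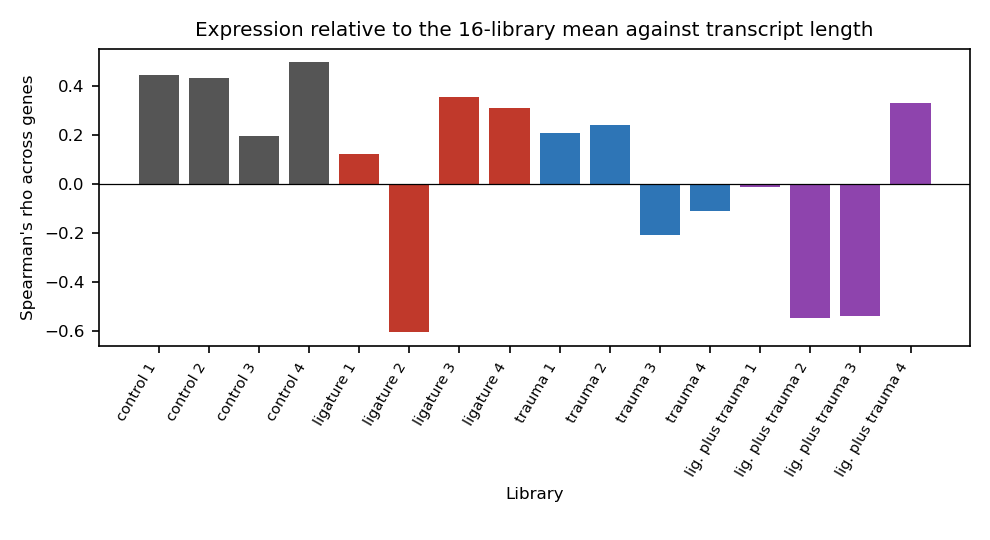
Rank correlation, across genes, of each library's expression (relative to the mean of all libraries) with transcript length, 1 value per library by group. Ligature 2 (-0.605) and ligature plus trauma 2 and 3 (-0.546 and -0.538) lie below the other 13 libraries, which range from -0.207 to 0.499.

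Ligature was compared with control to ask what the ligature changed in the tissue. Saa3 (ENSMUSG00000040026.9), an acute-phase serum amyloid A gene, rose from 0.517 ± 0.309 CPM (mean ± SD, n = 4) to 7508 ± 5071 CPM. Its log2 fold change was 13.81 ± 1.09 (SE; edgeR adjusted p = 6.17e-06). The matrix protease Mmp3 rose by 9.81 ± 0.86 (edgeR adjusted p = 2.23e-05) from 1.12 ± 0.595 to 1005 ± 254 CPM, and the cytokine Il6 by 9.37 ± 1.48 (edgeR adjusted p = 0.00123), from 0.0893 ± 0.148 to 61.3 ± 18.1 CPM. Saa1, whose reads can be shared with near-identical genes, rose by 7.39 ± 1.12 and Rln1, which encodes a relaxin, by 5.17 ± 1.02. Genes of the upper layers of stratified epithelium lay at the other end: Krt4 (log2 fold change -9.69 ± 2.26), Lor (-7.99 ± 1.67), Lce3f (-7.06 ± 1.54), Serpinb3a (-6.91 ± 1.92) and Krt13 (-6.60 ± 1.48), with edgeR adjusted p from 0.00683 (Lor) to 0.0315 (Serpinb3a). In all 2234 genes passed, 1233 higher and 1001 lower, and 1859 of them differed at least 2-fold.

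Genes of bone-resorbing cells rose. Of 17 osteoclast genes, 12 rose and none fell over all genes tested, and 15 rose when adjusted over the list alone (median log2 fold change 2.21, camera adjusted p = 1.93e-18, adjusted p = 0.0691 with an estimated correlation). Ctsk, the collagen-degrading cathepsin of osteoclasts, went from 1855 ± 964 to 7987 ± 1295 CPM (log2 fold change 2.11 ± 0.40, edgeR adjusted p = 0.00372). Acp5, the tartrate-resistant phosphatase that marks them, rose by 2.36 ± 0.46 (edgeR adjusted p = 0.0042), Tcirg1, part of their proton pump, by 2.39 ± 0.27, and the cell-fusion genes Ocstamp and Dcstamp by 3.01 ± 0.40 and 2.94 ± 0.48. Osteoclastogenic and resorption signals were mixed: 4 of 19 rose and 1 fell, or 8 and 2 when adjusted over the list alone (median 0.86, camera adjusted p = 0.0227, adjusted p = 0.214 with an estimated correlation). The member that fell was Il34 (-1.73 ± 0.24), a ligand of the receptor for colony-stimulating factor 1. Tnfsf11, which encodes RANKL, the main osteoclast-inducing ligand, was at 19.0 ± 14.3 CPM in control and 84.5 ± 14.4 CPM in ligature without passing (2.15 ± 0.75, edgeR adjusted p = 0.0755). Its decoy receptor Tnfrsf11b was at -0.61 ± 0.39 (edgeR adjusted p = 0.341).

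Bone-forming genes went the other way. Of 18 osteoblast genes, 12 fell and none rose, 14 when adjusted over the list alone (median -1.42, camera adjusted p = 2.7e-10, adjusted p = 0.0691 with an estimated correlation). Bglap, the osteocalcin gene, went from 2222 ± 918 to 363 ± 153 CPM (-2.61 ± 0.38, edgeR adjusted p = 0.000792). Its near-identical copy Bglap2 fell by 2.71 ± 0.39 on the log2 scale, the transcription factor Dlx5 by 1.44 ± 0.24 and Smpd3, a sphingomyelinase needed for mineralisation, by 3.05 ± 0.56. Sost, the Wnt inhibitor made by osteocytes, did not pass (-3.17 ± 1.07, edgeR adjusted p = 0.069). In the ligament fibroblast list 5 of 18 fell and 1 rose, or 6 and 1 when adjusted over the list alone (median -0.60, camera adjusted p = 0.000379, adjusted p = 0.296 with an estimated correlation). Thbs4 (-2.94 ± 0.36) and Tnmd (-1.61 ± 0.30), matrix and membrane proteins of tendon and ligament, were among the fallen, and the collagen gene Col12a1 (1.39 ± 0.25) was the riser. The fibroblast marker Postn did not pass (-0.49 ± 0.45, edgeR adjusted p = 0.521). Wnt targets and regulators fell in 3 of 18 and rose in 1, or 8 and 1 when adjusted over the list alone (median -0.69, camera adjusted p = 0.0124, adjusted p = 0.0704 with an estimated correlation). The ligand gene Wnt10b changed by -2.96 ± 0.50 and the Wnt antagonist Sfrp4 by 2.96 ± 0.46.

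Inflammatory and neutrophil genes rose. Of 21 inflammatory cytokines and chemokines 10 rose, 13 when adjusted over the list alone (median 2.47, camera adjusted p = 7.19e-11, adjusted p = 0.0873 with an estimated correlation). Among them were the chemokines Ccl2 (5.12 ± 0.90) and Ccl3 (3.82 ± 0.66), and Il1b rose by 2.70 ± 0.54 (edgeR adjusted p = 0.00538). Mature neutrophil genes rose in 11 of 17, 13 over the list alone (median 2.26, camera adjusted p = 1.24e-12, adjusted p = 0.0873 with an estimated correlation), for example the pattern receptors Clec4e (3.15 ± 0.50) and Clec4d (3.63 ± 0.65). Endothelial genes rose in 10 of 16, or 11 with 1 lower when adjusted over the list alone (median 1.21, camera adjusted p = 2.05e-09, adjusted p = 0.0704 with an estimated correlation), led by the adhesion molecules Selp (4.82 ± 0.63) and Sele (3.56 ± 0.69). Matrix-degrading proteases and inhibitors rose in 8 of 23 and fell in 1 (10 and 1 over the list alone, median 0.86, camera adjusted p = 3.28e-06, adjusted p = 0.0916 with an estimated correlation), with Timp1 at 3.71 ± 0.59, Mmp9 at 2.04 ± 0.33 and the collagenase Mmp13 at 2.23 ± 0.56 (edgeR adjusted p = 0.0194, or 0.0508 when only the compared groups were fitted). Cell cycle genes rose in 17 of 20, all 20 over the list alone (median 1.69, camera adjusted p = 2.77e-20, adjusted p = 0.0691 with an estimated correlation), among them the replication gene Mcm5 (2.25 ± 0.28) and Cdk1 (2.50 ± 0.37). Nuclear oxidative phosphorylation genes rose in 12 of 20, 19 over the list alone (median 1.09, camera adjusted p = 5.44e-12, adjusted p = 0.0916 with an estimated correlation). These are mostly short transcripts, and removing the length trend lowered their median to 0.71. Of 18 interferon-stimulated genes 2 passed, and 2 over the list alone, with Oas1a at 1.74 ± 0.52. Oas1a lost its call without any 1 of the controls or ligature 1, 2 or 4 (edgeR adjusted p = 0.0599 to 0.163). That list (median 0.83, camera adjusted p = 0.0275, adjusted p = 0.497 with an estimated correlation) lost its call without ligature 2 (camera adjusted p = 0.33) and with the replicate block (0.0586).

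Other tissues moved with the ligature too. Oral epithelium genes fell in 8 of 22 and rose in 1, or 16 and 1 when adjusted over the list alone (median -1.62, camera adjusted p = 1.67e-05, adjusted p = 0.444 with an estimated correlation). Dsp, which encodes the desmosome protein desmoplakin, fell by 2.19 ± 0.60 on the log2 scale, and Krt1 was at -11.06 ± 2.17. The calls of Krt1, Krt4, Lor, Lce3f, Serpinb3a and Il6 were lost with voom (adjusted p = 0.335, 0.146, 0.216, 0.249, 0.256 and 0.0732). Serpinb3a also lost its call without control 2 (0.0801), ligature 1 (0.0818), ligature 2 (0.0704) or ligature 4 (0.0613). Schwann cell genes fell in 6 of 16, 9 over the list alone (median -1.34, camera adjusted p = 0.000294, adjusted p = 0.133 with an estimated correlation), for example the myelin gene Mbp (-1.80 ± 0.33). Odontoblast, pulp and enamel organ genes fell in 3 of 13, 4 over the list alone (median -1.62, camera adjusted p = 0.00012, adjusted p = 0.0873 with an estimated correlation), such as Odam (-3.01 ± 0.48), a gene of the epithelium that attaches gum to tooth. Cartilage genes fell in 3 of 12, 4 over the list alone (median -1.66, camera adjusted p = 0.00108, adjusted p = 0.0873 with an estimated correlation), including Hapln1 (-2.53 ± 0.44). By fry the lists that camera called in ligature against control kept their calls, for example osteoclast (fry adjusted p = 0.000411) and osteoblast genes (0.000283). The exceptions were oral epithelium (0.101) and interferon-stimulated genes (0.138). Fry also called adipocyte genes lower (0.0168) and endoplasmic reticulum stress genes higher (0.00721). The count of 2234 genes was 1470 without ligature 1, 1474 without control 1 and 1304 when only the compared groups were fitted, and DESeq2 called 3859.

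**Figure D2:**
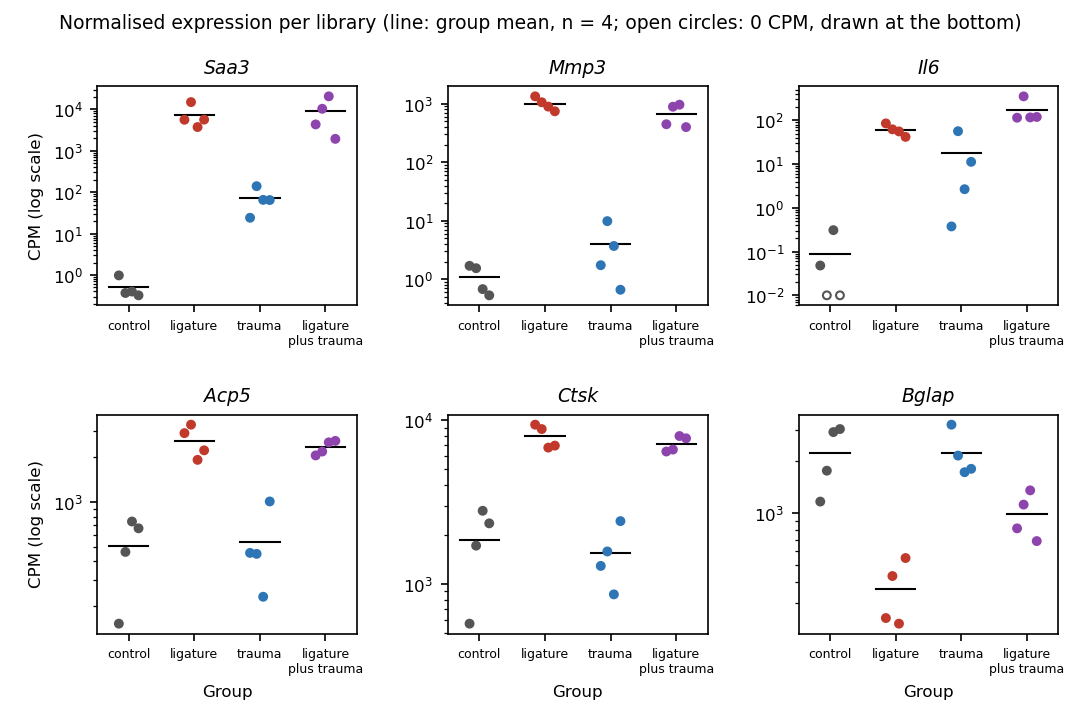
CPM (log axis) of single genes in each of the 16 libraries, 1 point per library, with a line at the group mean (n = 4 per group). Open circles mark 0. Saa3, Mmp3, Il6, Acp5 and Ctsk lay higher and Bglap lower in ligature than in control.

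Trauma was compared with control to ask what occlusal overload changed without a ligature. A single gene passed, Saa3, at 73.5 ± 48.3 CPM against 0.517 ± 0.309 CPM (log2 fold change 7.14 ± 0.86, edgeR adjusted p = 0.00684). It was higher in trauma in all 16 pairs of libraries, with trauma libraries at 24.1 to 140 CPM. Reads carried over from ligature libraries were not excluded for Saa3. The call was lost without control 4 (edgeR adjusted p = 0.0765) and with voom (adjusted p = 0.176), and DESeq2 called 127 genes. None of the bone genes of the panel passed. Acp5 differed by 0.09 on the log2 scale (95% interval -0.83 to 1.003), Ctsk by -0.27 (-1.08 to 0.54), Bglap by 0.00 (-0.76 to 0.76), Postn by -0.13 (-1.08 to 0.81), Sost by -0.13 (-2.20 to 1.95), Mmp13 by -0.45 (-1.60 to 0.69) and Tnfrsf11b by 0.45 (-0.38 to 1.28), intervals that leave moderate changes open. Il6 (7.58 ± 1.39, edgeR adjusted p = 0.217), Il1b (2.11 ± 0.53, 0.449) and Tnfsf11 (1.58 ± 0.73, 0.715) were higher in trauma without passing. An unadjusted p under 0.05 was reached by 1450 genes, where chance gives 1048. That excess depended on single libraries: the number was 924 without trauma 3 and 994 without control 4, and it was 2557 with voom and 3126 in the 13 libraries.

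As groups, inflammatory and neutrophil genes nevertheless lay higher with trauma. All 21 inflammatory cytokines and chemokines had a positive log2 fold change, none passing over all genes and 13 when adjusted over the list alone (median 2.02, camera adjusted p = 2.47e-19, adjusted p = 0.116 with an estimated correlation), for example Ccl2 (3.40 ± 0.83) and Ptgs2 (2.08 ± 0.55). Of 17 mature neutrophil genes 16 were positive and 11 passed over the list alone (median 1.64, camera adjusted p = 4.87e-19, adjusted p = 0.116 with an estimated correlation), with S100a8 at 3.14 ± 0.72 and S100a9 at 2.89 ± 0.64. Resorption signals, which share members with the inflammatory list, had 3 of 19 past the list-alone test (median 0.79, camera adjusted p = 0.000101, adjusted p = 0.116 with an estimated correlation). Cell cycle genes had 6 of 20 (median 0.55, camera adjusted p = 0.000101, adjusted p = 0.504 with an estimated correlation, lost without trauma 3 at 0.0846), with Mcm5 at 1.35 ± 0.28. Hypoxia and glycolysis genes had none (median 0.48, camera adjusted p = 0.000301, adjusted p = 0.176 with an estimated correlation). By fry no list passed in trauma against control (lowest fry adjusted p = 0.0525, inflammatory and neutrophil genes among them). The osteoclast list did not pass (median -0.32, camera adjusted p = 0.0706), but it was called lower without control 1 (0.000193) or trauma 4 (0.000289) and with the replicate block (0.0456).

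Other list calls depended on single libraries or on the setting, and some of them concerned genes of other tissues. Skeletal muscle genes, whose score was lower in all 4 trauma libraries than in control 3, had a median of -3.36 with none of 19 positive (camera adjusted p = 5.61e-05, adjusted p = 0.504 with an estimated correlation), and the call was lost without control 3 (0.0686). The epithelium list was higher (median 0.84, camera adjusted p = 0.000301, adjusted p = 0.504 with an estimated correlation), a call lost without control 4 (0.188) or trauma 3 (0.174). The osteoblast list (median -0.43, camera adjusted p = 0.0068) lost its call without control 3 (0.0686), control 4 (0.0608) or trauma 2 (0.0588), and the ligament fibroblast list (median -0.31, camera adjusted p = 0.00879) without control 3 (0.0954), control 4 (0.0684) or trauma 3 (0.0624). Both had adjusted p = 0.504 with an estimated correlation. Oxidative phosphorylation (median 0.39, camera adjusted p = 0.000574, adjusted p = 0.504 with an estimated correlation) lost its call when the length trend was removed (0.134). Interferon-stimulated genes (median 0.60, camera adjusted p = 0.019) lost theirs without control 3 (0.0686) or trauma 4 (0.328), and matrix proteases (median 0.11, camera adjusted p = 0.046) without control 1 (0.287), control 3 (0.0686), trauma 2 (0.31) or trauma 4 (0.382), with adjusted p = 0.504 for both with an estimated correlation. Immediate-early genes (median 0.27, camera adjusted p = 0.0466, adjusted p = 0.546 with an estimated correlation) lost theirs without control 2 (0.0761), control 3 (0.307), trauma 2 (0.344) or trauma 4 (0.232). Other lists did not pass with all libraries and were called in other settings. Mitochondrially encoded genes (camera adjusted p = 0.804) were called lower with the length trend removed (3.62e-06), with the length slope as a covariate (0.000311) and without control 1 (0.036). Erythroid genes (0.0875) were called lower with the trend removed (0.0207), with the covariate (0.00286) and without control 1 (0.00856), control 2 (0.0457) or trauma 1 (0.00201). Cartilage (0.0642), collagen (0.23), Schwann cell (0.0857) and granulocyte precursor genes (0.237) were called lower, and antigen presentation genes (0.0851) higher, when 1 library was left out. Their lowest values were 0.0222, 0.0146 and 0.031 without control 1 for cartilage, collagen and precursors, 0.0347 without trauma 2 for Schwann cell and 0.0135 without trauma 1 for antigen presentation.

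**Figure D3:**
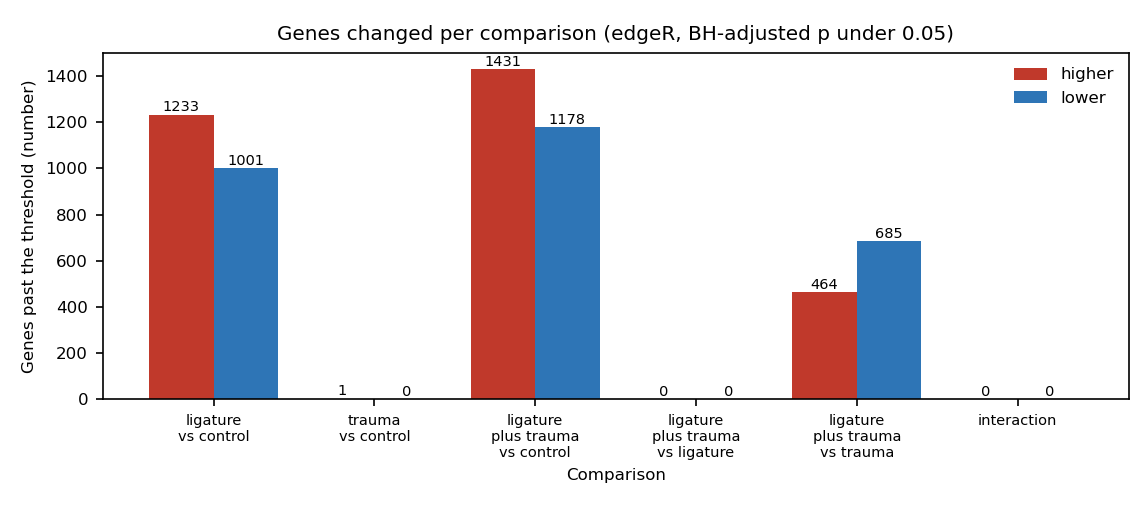
Number of genes higher and lower in each comparison (edgeR, adjusted p under 0.05, 20953 genes tested, n = 4 libraries per group). Comparisons that differ by the ligature held 1149 to 2609 genes, whereas adding trauma gave 1 gene without and 0 with the ligature.

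Ligature plus trauma was compared with control to describe both together. Saa3 was at 9321 ± 8344 CPM (log2 fold change 14.13 ± 1.10, edgeR adjusted p = 5.08e-06). Il6 rose by 10.89 ± 1.55 (edgeR adjusted p = 0.000971), Mmp3 by 9.23 ± 0.85, Saa1 by 7.51 ± 1.13 and Rln1 by 5.47 ± 1.03. Among the genes that fell furthest were the diamine oxidase gene Aoc1 (-6.05 ± 1.0, edgeR adjusted p = 0.00197) and Them5, which encodes a thioesterase (-5.94 ± 0.92, edgeR adjusted p = 0.00145). The epithelial genes Lor, Serpinb12 and Calm4 fell as well (-7.04 ± 1.59, -6.09 ± 1.51 and -5.63 ± 1.40, edgeR adjusted p = 0.0114, 0.0186 and 0.0189). In all 2609 genes passed, 1431 higher and 1178 lower, 2142 of them by at least 2-fold. Voom did not call Aoc1 (adjusted p = 0.129), Them5 (0.0668), Lor (0.269), Serpinb12 (0.258) or Calm4 (0.115). Serpinb12 also lost its call without control 2 (0.0584) or ligature plus trauma 2 (0.0505), and Calm4 without control 2 (0.0681), ligature plus trauma 2 (0.0523) or 3 (0.0665). In the 13 libraries Lor (0.128), Serpinb12 (0.131) and Calm4 (0.161) were not called.

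Osteoclast genes rose in 10 of 17, 13 over the list alone (median 1.95, camera adjusted p = 7.97e-14, adjusted p = 0.112 with an estimated correlation), with Ctsk at 7189 ± 787 CPM (1.95 ± 0.40, edgeR adjusted p = 0.00663) and Acp5 at 2340 ± 254 CPM (2.21 ± 0.45, edgeR adjusted p = 0.00714). Tnfsf11 did not pass (2.25 ± 0.75, edgeR adjusted p = 0.0601), nor did Tnfrsf11b (-0.23, edgeR adjusted p = 0.727), Sost (-2.27, 0.148) and Postn (0.02, 0.986). Resorption signals rose in 6 of 19 and fell in 1, or 8 and 2 over the list alone (median 0.37, camera adjusted p = 0.0169, adjusted p = 0.221 with an estimated correlation), with Il34 at -1.99 ± 0.24. Osteoblast genes fell in 10 of 18, 14 over the list alone (median -1.18, camera adjusted p = 2.1e-07, adjusted p = 0.112 with an estimated correlation). Smpd3 was at -3.08 ± 0.56 (lost in the 13 libraries, edgeR adjusted p = 0.0537) and the collagen gene Col1a1 at -1.56 ± 0.26. Bglap was at 990 ± 299 CPM (-1.17 ± 0.36, edgeR adjusted p = 0.0464). That call was lost without control 2, 3 or 4 or any of the 4 libraries of ligature plus trauma (edgeR adjusted p = 0.0607 to 0.124), and with the replicate block (0.074). Mmp13 (1.87 ± 0.56, edgeR adjusted p = 0.0394) lost its call with any 1 of the 8 libraries left out (0.0544 to 0.0879) and with the replicate block (0.0558).

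Neutrophil genes rose in 15 of 17, 15 over the list alone too (median 2.78, camera adjusted p = 2.54e-15, adjusted p = 0.112 with an estimated correlation), with Clec4d at 4.51 ± 0.68 and the calprotectin genes S100a8 and S100a9 at 2.73 ± 0.71 and 2.31 ± 0.62. Inflammatory genes rose in 9 of 21, 12 over the list alone (median 2.01, camera adjusted p = 6.31e-11, adjusted p = 0.119 with an estimated correlation), among them Ccl2 (5.40 ± 0.91), Ccl3 (4.69 ± 0.69) and Il1b (3.48 ± 0.56, edgeR adjusted p = 0.00172). Cell cycle genes rose in 12 of 20, 18 over the list alone (median 1.27, camera adjusted p = 2.6e-13, adjusted p = 0.112 with an estimated correlation). Oxidative phosphorylation genes rose in 17 of 20, all 20 over the list alone (median 1.26, camera adjusted p = 4.6e-13, adjusted p = 0.119 with an estimated correlation), and the median was 0.68 with the length trend removed, 0.56 with the length slope as a covariate and 0.72 in the 13 libraries. Endothelial genes rose in 8 of 16, 9 over the list alone (median 0.99, camera adjusted p = 2.7e-08, adjusted p = 0.112 with an estimated correlation). Matrix proteases rose in 10 of 23 and fell in 1, or 11 and 1 over the list alone (median 1.05, camera adjusted p = 4.04e-06, adjusted p = 0.119 with an estimated correlation). Immediate-early genes rose in 5 of 20, 7 over the list alone (median 0.62, camera adjusted p = 0.0037, adjusted p = 0.404 with an estimated correlation), led by Fos (1.78 ± 0.39, edgeR adjusted p = 0.00929).

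Epithelium genes fell in 13 of 22, or 20 with 1 higher over the list alone (median -2.45, camera adjusted p = 3.24e-07, adjusted p = 0.358 with an estimated correlation), with Dsp at -2.73 ± 0.61, a call lost in the 13 libraries (edgeR adjusted p = 0.135). Cartilage genes fell in 3 of 12, 3 over the list alone (median -1.60, camera adjusted p = 0.0057, adjusted p = 0.119 with an estimated correlation). Odontoblast, pulp and enamel organ genes fell in 2 of 13, 3 over the list alone (median -1.27, camera adjusted p = 0.0116, adjusted p = 0.239 with an estimated correlation), with Odam at -2.99 ± 0.48. Ligament fibroblast genes fell in 3 of 18 and rose in 1, or 5 and 1 over the list alone (median -0.54, camera adjusted p = 0.0105, adjusted p = 0.457 with an estimated correlation), with Thbs4 at -2.55 ± 0.36, and the list's call was lost in the 13 libraries (0.117). Interferon-stimulated genes (3 of 18 higher, median 0.70, camera adjusted p = 0.00618, adjusted p = 0.374 with an estimated correlation) lost theirs there too (0.137). Mitochondrially encoded genes (none of 13 passing, median 0.35, camera adjusted p = 0.0329, adjusted p = 0.689 with an estimated correlation) lost theirs without control 1 (0.264), control 2 (0.0733) or ligature plus trauma 2 (0.228) and in the 13 libraries (0.666). With the length trend removed they tested lower instead (median -0.16, camera adjusted p = 0.244). Lists not passing were called in other settings: Wnt (0.0788) and antigen presentation genes (0.985) lower with the length slope as a covariate (0.0427 and 0.0112), Schwann cell genes (0.087) lower without control 1 (0.0484) or ligature plus trauma 4 (0.0259), and endoplasmic reticulum stress genes (0.113) higher in the 13 libraries (0.0213). The count of 2609 was 819 in the 13 libraries (546 higher, 273 lower), which hold 2 libraries of ligature plus trauma, 1160 with the length slope as a covariate and 2538 with the length trend removed. It was 1057 without ligature plus trauma 3, 1145 without ligature plus trauma 2, 1335 without control 2, 1372 without control 1 and 1597 without control 4, and DESeq2 called 4470.

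**Figure D4:**
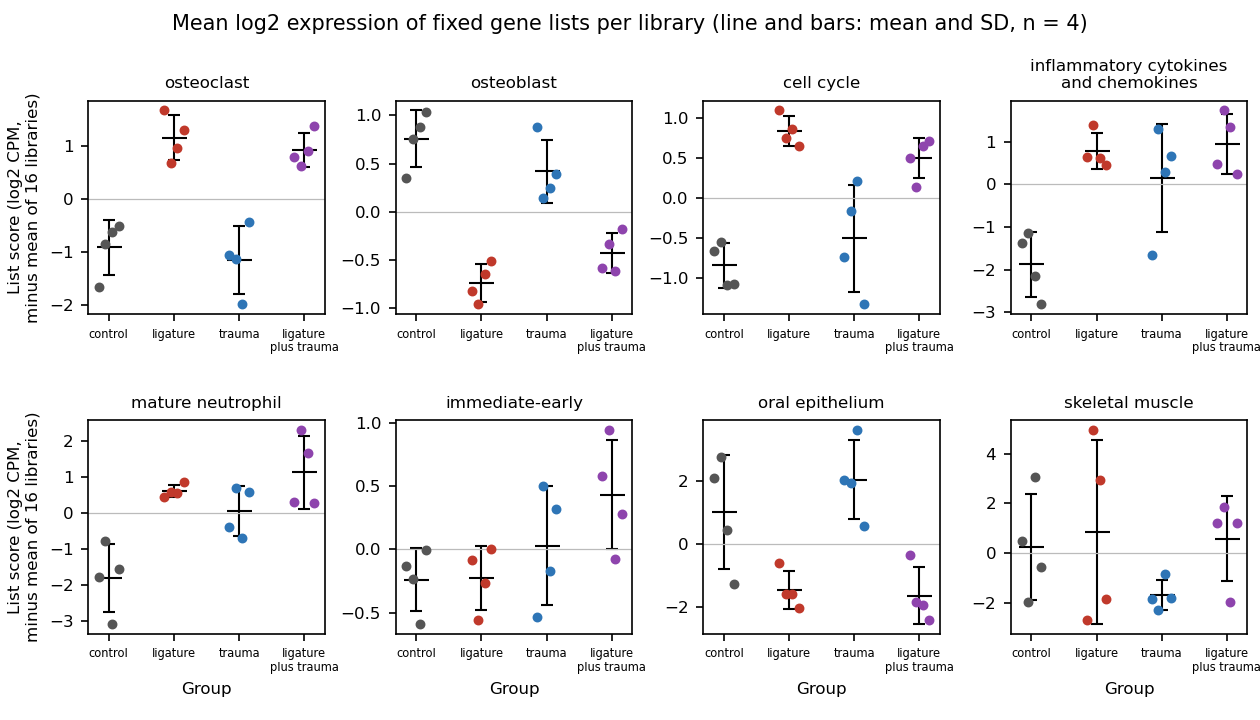
Scores of gene lists (mean log2 CPM of the members relative to the mean of all 16 libraries), 1 point per library by group, with a line at the group mean (n = 4 per group). The osteoclast score averaged -0.911 in control and -1.15 in trauma against 1.15 in ligature and 0.915 in ligature plus trauma; the neutrophil score of trauma (0.0457) lay between control (-1.81) and ligature (0.621).

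Ligature plus trauma was compared with ligature to ask what traumatic occlusion added once a ligature was in place, the question in the title of the series. No gene passed with edgeR (smallest adjusted p = 0.919), nor with voom, while DESeq2 called 45. An unadjusted p under 0.05 was reached by 734 genes, fewer than the 1048 that chance gives, but by 2774 without ligature 2 and by 2041 with voom. The 3 genes with the lowest p were Gpr22, Fsip1 and Irx2, with low mean log2 CPM of -2.21, -0.13 and -1.76. Gpr22 had 0 counts in all ligature libraries and 0.436 ± 0.478 CPM (n = 4) in ligature plus trauma, Fsip1 went from 0.178 ± 0.116 to 1.59 ± 0.816 CPM (log2 fold change 3.14 ± 0.64), and Irx2 from 0.309 ± 0.220 CPM to 0 counts. Ctsk differed by -0.15 (95% interval -0.96 to 0.66), Acp5 by -0.15 (-1.07 to 0.77), Tnfsf11 by 0.10 (-1.42 to 1.61), Tnfrsf11b by 0.37 (-0.46 to 1.20), Mmp13 by -0.37 (-1.51 to 0.77), Postn by 0.51 (-0.44 to 1.46), Sost by 0.89 (-1.24 to 3.03), Il1b by 0.78 (-0.30 to 1.86) and Il6 by 1.52 (-0.61 to 3.65). Of these intervals only that of Ctsk excluded both a 2-fold rise and a 2-fold fall. Bglap (1.45 ± 0.37, interval 0.67 to 2.22) and Il6 were higher with trauma in all 16 pairs of libraries without passing over all genes (edgeR adjusted p = 1 for both).

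Several lists shifted by small amounts here by camera, and none passed by fry (lowest fry adjusted p = 0.464). Immediate-early genes, which cells switch on within minutes of a stimulus, were positive in 19 of 20, with 1 past the list-alone test (median 0.58, camera adjusted p = 8.47e-11, adjusted p = 0.466 with an estimated correlation). Nr4a3 was at 2.14 ± 0.58, Nr4a1 at 1.33 ± 0.52 and Fos at 0.93 ± 0.38. For Nr4a1, ligature 2 lay low, at 2.18 log2 CPM against 4.16 to 4.37 in the other ligature libraries. Cell cycle genes were lower (median -0.32, camera adjusted p = 0.0006, adjusted p = 0.808 with an estimated correlation). Schwann cell genes were higher (median 0.52, 2 over the list alone, camera adjusted p = 0.0006, adjusted p = 0.744 with an estimated correlation), a call lost without ligature 2 (0.106) or ligature plus trauma 4 (0.121). Neutrophil genes were positive in 17 of 17 (median 0.82, camera adjusted p = 0.00277, adjusted p = 0.808 with an estimated correlation). That call was lost without ligature 2 (0.0679), ligature plus trauma 2 (0.587) or ligature plus trauma 3 (0.0561), and in the 13 libraries the median was -0.48. The inflammatory list did not pass (median 0.28, camera adjusted p = 0.386). The osteoclast list (median -0.34, camera adjusted p = 0.03) lost its call without ligature 1 (0.53), ligature 4 (0.0604), ligature plus trauma 1 (0.153) or 2 (0.236). The osteoblast list (median 0.04, 2 higher over the list alone, camera adjusted p = 0.0499) lost it without ligature 1 (0.179), ligature 2 (0.626), ligature plus trauma 1 (0.104), 2 (0.0893) or 4 (0.276), with the replicate block (0.0564), with median-ratio (RLE) size factors in place of TMM (0.0528), with the length trend removed (0.163) and in the 13 libraries (0.202). Both had adjusted p = 0.808 with an estimated correlation. The mitochondrially encoded (median 0.33), odontoblast (0.52) and osteocyte lists (0.47) were higher and the collagen (-0.16) and muscle lists (-2.16) lower, with camera adjusted p of 0.00394, 0.0283, 0.0499, 0.0283 and 0.0386, all 0.808 with an estimated correlation. Each lost its call on leaving out single libraries, at most to 0.341 (ligature plus trauma 2), 0.397 (ligature 2), 0.733 (ligature 2), 0.305 (ligature 3) and 0.585 (ligature plus trauma 3). The muscle list had no stable direction: it tested higher in the 13 libraries (camera adjusted p = 0.0274, median -0.04) and without ligature 2 (0.362), and lost its call with the replicate block (0.477, median -0.79). Of the other 4 all lost their calls in the 13 libraries (0.202 to 0.403). Ligament fibroblast genes (camera adjusted p = 0.127) were called higher with the length trend removed (0.0464), with the length slope as a covariate (0.0131) and without ligature 3 (0.00158) or ligature plus trauma 3 (0.013), and erythroid genes (0.292) in the 13 libraries (0.014) and without ligature 2 (0.0221). Epithelium genes (0.159) were called lower without ligature 4 (0.0213) or ligature plus trauma 1 (0.000608), and T and NK cell genes (0.292) without ligature 4 (0.0461) or ligature plus trauma 3 (0.0293). Interferon-stimulated (0.292) and oxidative phosphorylation genes (0.356) were called higher without ligature 2 (0.0125 and 0.00446) or ligature plus trauma 4 (0.0355 and 0.0487).

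Ligature plus trauma was compared with trauma to ask what the ligature changed in overloaded teeth. Mmp3 rose by 7.39 ± 0.78 (edgeR adjusted p = 0.000386), Saa3 by 6.99 ± 0.84 (edgeR adjusted p = 0.000979), Bdh2, a dehydrogenase gene of ketone metabolism, by 3.26 ± 0.51 and S100a4, a calcium-binding protein gene of motile cells, by 3.25 ± 0.71. Epithelial genes fell furthest: Serpinb12 (-7.49 ± 1.61, edgeR adjusted p = 0.0137), Lor (-7.35 ± 1.61, 0.0153) and Krt13 (-7.23 ± 1.53, 0.0129). Rln1 (3.67 ± 0.94), Krt4 (-7.94 ± 2.09) and Serpinb3a (-7.68 ± 1.98) passed with all libraries and not without trauma 1, trauma 3, ligature plus trauma 2 or ligature plus trauma 3 (edgeR adjusted p = 0.0523 to 0.106). The same held for Krt4 and Serpinb3a without ligature plus trauma 4 (0.067 and 0.0853), for Rln1 without trauma 2 (0.069) and for Lor without ligature plus trauma 2 (0.0505) or 3 (0.0547). Voom called none of Krt4 (adjusted p = 0.225), Krt13 (0.0519), Lor (0.276), Serpinb12 (0.306) and Serpinb3a (0.322). In all 1149 genes passed, 464 higher and 685 lower, 1047 of them by at least 2-fold.

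Osteoclast genes rose in 12 of 17, 13 over the list alone (median 2.13, camera adjusted p = 4.91e-25, adjusted p = 0.055 with an estimated correlation), Ctsk by 2.23 ± 0.40 (edgeR adjusted p = 0.00566), Acp5 by 2.12 ± 0.45 (edgeR adjusted p = 0.0132), Tcirg1 by 2.21 ± 0.27 and Dcstamp by 3.19 ± 0.48. Mmp13 rose by 2.32 ± 0.56 (edgeR adjusted p = 0.0247), a call lost without trauma 1 (0.0729), trauma 3 (0.073) or ligature plus trauma 4 (0.0616). Il1b (1.37 ± 0.52, edgeR adjusted p = 0.149), Bglap (-1.17 ± 0.36, 0.0776), Tnfsf11 (0.67, 0.683), Sost (-2.15, 0.265) and Tnfrsf11b (-0.69, 0.367) did not pass, and neither did Il6 (edgeR adjusted p = 0.0894) or Postn (0.15 on the log2 scale). Endothelial genes rose in 8 of 16, or 12 with 1 lower over the list alone (median 1.04, camera adjusted p = 1.93e-10, adjusted p = 0.0753 with an estimated correlation), Selp by 3.02 ± 0.58. Oxidative phosphorylation genes rose in 6 of 20, 13 over the list alone (median 0.80, or 0.36 in the 13 libraries, camera adjusted p = 7.27e-10), cell cycle genes in 5 of 20, 10 over the list alone (median 0.96, camera adjusted p = 3.87e-09), and matrix proteases in 6 of 23 with 1 lower, 8 and 2 over the list alone (median 0.65, camera adjusted p = 4.43e-05), with Timp1 at 2.85 ± 0.57. Osteoblast genes fell in 3 of 18, 6 over the list alone (median -0.64, camera adjusted p = 3.39e-05), with Smpd3 at -2.58 ± 0.55. These 4 lists each had adjusted p = 0.187 with an estimated correlation.

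Epithelium genes fell in 16 of 22, 21 over the list alone (median -2.86, camera adjusted p = 1.91e-17, adjusted p = 0.187 with an estimated correlation), with Dsp at -3.48 ± 0.63. Left with 2 libraries of ligature plus trauma, the 13 libraries did not call Dsp (0.09), Smpd3 (0.138), Krt13 (0.142), Lor (0.156), Serpinb12 (0.116) or Acp5 (0.068). Muscle genes were higher with none passing and 2 over the list alone (median 3.19, camera adjusted p = 0.000571, adjusted p = 0.617 with an estimated correlation), beside muscle scores of 1.2, 1.85, -1.95 and 1.23 in the libraries of ligature plus trauma. Neutrophil genes rose in 3 of 17, 7 over the list alone (median 1.34, camera adjusted p = 5.02e-05, adjusted p = 0.465 with an estimated correlation). In the 13 libraries their median was 0.19 (camera adjusted p = 0.477). Inflammatory genes were positive in 11 of 21, with 2 passing and 3 over the list alone (median 0.90, camera adjusted p = 0.0458, adjusted p = 0.617 with an estimated correlation). That call was lost without trauma 1 (0.711), ligature plus trauma 2 (0.224) or 3 (0.0712), with the length trend removed (0.106) and in the 13 libraries (0.834). Hypoxia genes fell in 2 of 20 (median -0.45, camera adjusted p = 0.0342, adjusted p = 0.43 with an estimated correlation), lost without trauma 2 (0.077), trauma 4 (0.0886), ligature plus trauma 1 (0.0854) or 4 (0.0528). The adipocyte list was lower (median -1.09, 2 of 11 fell, 2 higher and 5 lower over the list alone, camera adjusted p = 0.0202, adjusted p = 0.163 with an estimated correlation), lost without ligature plus trauma 1 (0.0809) and with the length trend removed (0.0553). Mitochondrially encoded genes were higher (median 0.50, camera adjusted p = 0.00716, adjusted p = 0.617 with an estimated correlation), lost without trauma 4 (0.0596) or ligature plus trauma 2 (0.115), with the length trend removed (0.196) and in the 13 libraries (0.565). Immediate-early genes did not pass (camera adjusted p = 0.054) and were called higher with RLE size factors (0.0491), the replicate block (0.0486) and the length slope as a covariate (0.0407), and without trauma 2 (0.00727), trauma 4 (0.0191) or ligature plus trauma 3 (0.00153) or 4 (0.0284). Odontoblast and cartilage genes (0.0577 each) were called lower without trauma 3 (0.00656 and 0.0451) or ligature plus trauma 4 (0.0463 and 0.0325), odontoblast genes also without trauma 4 (0.0486) and cartilage genes with the replicate block (0.0486). Antigen presentation genes (0.212) were called lower with the covariate (0.00723) and in the 13 libraries (0.0194). Interferon-stimulated genes (0.136) were called higher without trauma 4 (0.0112) or ligature plus trauma 4 (0.0211), and erythroid genes (0.265) without trauma 1 (0.0168). The count of 1149 was 447 in the 13 libraries (286 higher, 161 lower), 1560 with the length trend removed and 1724 with the length slope as a covariate. It was 584 without ligature plus trauma 3, 585 without ligature plus trauma 2, 587 without trauma 3, 708 without ligature plus trauma 4 and 723 without trauma 1. Voom called 506 higher and 426 lower, and DESeq2 called 2165.

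The ligature's effect was set side by side in mice with and without trauma, 2 comparisons that share no library. Across 11691 genes, which are not independent replicates, the log2 fold changes correlated with Pearson's r = 0.809 and Spearman's rho = 0.785. Of all 20953 genes tested, 386 were higher in both, where independent lists would share 27.3, and 379 lower in both, where they would share 32.72, and 1 passed in opposite directions. The 3 libraries shifted to short transcripts all carried a ligature, so their shift enters both comparisons, and the overlap without them was not computed. In the 13 libraries 1592 of the 2234 calls without trauma and 357 of the 1149 with trauma were made again. The effects of trauma without and with the ligature, which also share no library, correlated with r = 0.189 and rho = 0.243.

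**Figure D5:**
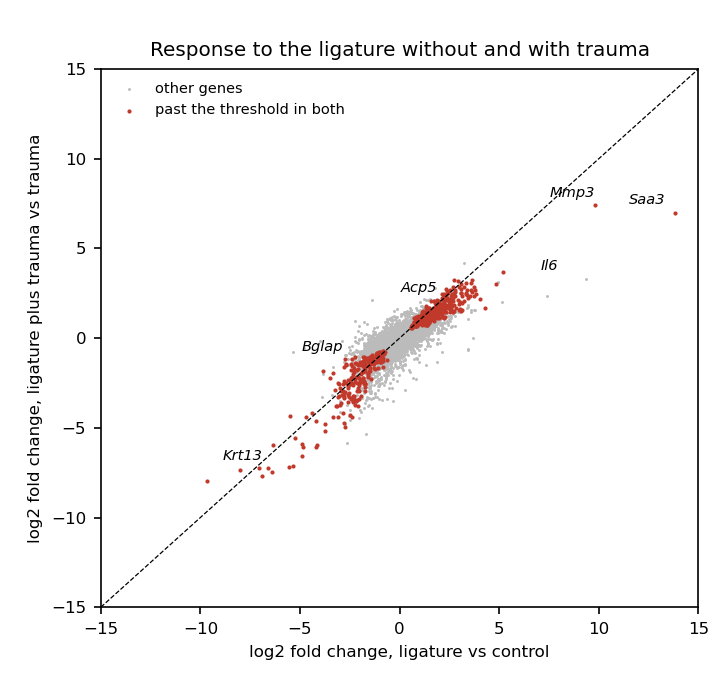
Log2 fold change of ligature against control (x axis) and of ligature plus trauma against trauma (y axis), 1 point per gene with a mean log2 CPM over 2, n = 4 libraries per group. Of all 20953 genes tested, also those not drawn, 386 passed as higher in both, 379 as lower in both and 1 in opposite directions. Across the genes with a mean log2 CPM over 2, r was 0.809.

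The interaction asked whether trauma acted differently with a ligature than without one. No gene passed with edgeR (smallest adjusted p = 0.108, 1032 genes at an unadjusted p under 0.05, where chance gives 1048, and 761 to 1351 with single libraries left out) or voom, while DESeq2 called 68. Saa3 had the lowest p: trauma went with a log2 fold change of 7.14 without the ligature, and the difference with the ligature was -6.83 ± 1.02 (edgeR adjusted p = 0.108). It passed without ligature plus trauma 3 (0.0412) and in the 13 libraries (0.0288). Next were Mcm5 (-1.98 ± 0.39, edgeR adjusted p = 0.554), at 5.01 ± 1.70, 23.8 ± 4.81, 12.8 ± 2.92 and 15.4 ± 3.13 CPM (n = 4 each) in control, ligature, trauma and ligature plus trauma, and Adnp, whose counts were near 0 in some libraries and high in others of the same group (13.6 ± 12.7, 0.106 ± 0.0849, 0.0101 ± 0.0202 and 18.3 ± 21.2 CPM). Of the panel, Il6 was at -6.06 ± 1.62 (edgeR adjusted p = 0.732), Bglap at 1.45 ± 0.51 (0.969), Il1b at -1.33 ± 0.72 (1), Tnfsf11 at -1.48 (95% interval -3.64 to 0.68), Acp5 at -0.24 (-1.53 to 1.06), Ctsk at 0.12 (-1.02 to 1.26), Postn at 0.64 (-0.70 to 1.98), Sost at 1.02 (-1.96 to 3.99), Mmp13 at 0.09 (-1.52 to 1.70) and Tnfrsf11b at -0.08 (-1.25 to 1.09). As lists, inflammatory genes had a lower effect of trauma on the log2 scale with the ligature than without (median -1.62, 0 of 21 positive, camera adjusted p = 2.8e-12, adjusted p = 0.225 with an estimated correlation), and so had cell cycle genes (median -0.79, 5 lower over the list alone, camera adjusted p = 1.38e-08, adjusted p = 0.243 with an estimated correlation) and neutrophil genes (median -1.14, camera adjusted p = 3.38e-07, adjusted p = 0.267 with an estimated correlation). Osteoblast genes differed the other way (median 0.61, camera adjusted p = 0.000233, adjusted p = 0.243 with an estimated correlation). These effects are ratios and do not say that trauma added fewer transcripts with the ligature. Mean CPM of Il6 went with trauma from 0.0893 ± 0.148 to 17.7 ± 26.3 (SD, n = 4) without the ligature and from 61.3 ± 18.1 to 176 ± 118 with it. In the last group Il6 was at 8.47 log2 CPM in ligature plus trauma 2, against 6.84 to 6.9 in the others. For Il1b the mean went from 68.3 ± 38.5 to 295 ± 154 and from 443 ± 108 to 760 ± 511. Differences in CPM were not tested. The osteoclast list did not pass (median 0.04, mean -0.05, camera adjusted p = 1). Lists that missed the threshold passed with single libraries left out, with lowest values of 0.0156 for T and NK cell (without ligature plus trauma 3), 0.013 for antigen presentation (without trauma 1), 0.00367 for matrix proteases (without trauma 3), 0.00723 for granulocyte precursors (without control 3) and 0.013 for osteocyte genes (without ligature 4 or trauma 1), against 0.0711, 0.0606, 0.0747, 0.0747 and 0.0815 with all.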

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

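Other splits of the libraries and the tests of the short-transcript libraries were written before their results were seen, except the test of depth, which was chosen after, as were the tests on inflammation in trauma and on epithelium.

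Splits of the 8 libraries of each comparison into 4 and 4 (35 splits) were fitted in the same way. Chance is argued against, as far as 35 splits can, for ligature against control (2234 genes, highest other split 1, with 1 split of 35 as large, the real one), ligature plus trauma against control (2609, highest other 0, 1 of 35) and ligature plus trauma against trauma (1149, highest other 1, 1 of 35). A share of 1 of 35 is the smallest these splits can give, and the number of comparisons was not allowed for. Splits that mix the groups also hold any real difference as spread, which lowers their counts. Chance cannot be excluded for the count of 1 gene in trauma against control, since 9 of 35 splits called as many and the highest other called 5. Those splits count any gene and do not test Saa3 itself. For ligature plus trauma against ligature and for the interaction the real count was 0, which any split reaches, so that splits decide nothing about chance there. In the former the highest other split called 2950 genes. This points to a structure of the samples: splits with ligature 2 and ligature plus trauma 2 and 3 on 1 side called 0 to 2950 genes, 3 of those 5 splits called any, and the other 30 called 0. For the interaction 95 of 100 drawn splits called 0 genes and 5 called any, the highest 1440, whose makeup was not examined.

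The counts of ligature 2 and of ligature plus trauma 2 and 3 were shifted to short transcripts, with rank correlations of -0.605, -0.546 and -0.538 across genes, below the lowest of the other 13 libraries (-0.207). A few abundant gene classes do not account for it, since without ribosomal protein, oxidative phosphorylation, mitochondrial, histone, globin and muscle genes the highest value of the 3 was still -0.513 over 11302 genes (other libraries -0.171 to 0.487). Lower depth does not either, since 4 of the other libraries (ligature 1, trauma 2 and 3 and ligature plus trauma 4) were no deeper than ligature 2 (63560698 counts) and lay at -0.207 to 0.333. Longer members were the lower ones in 26 of 31 lists (83.9%), as differences in RNA integrity or library making might produce, and these stay open. All 3 libraries carried a ligature, and no biological explanation was tested.

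In trauma against control the inflammatory and neutrophil lists lay higher (medians 2.02 and 1.64) although no member passed over all genes. Reads carried over from ligature libraries would give every gene 1 common share. The share was the excess of trauma over control as a percent of the excess of the libraries with a ligature. It was 0.344% for Mmp3 and 0.867% for Saa3, the reference genes. Over 21 list members, those called higher in ligature against control, its median was 31.8% (quartiles 22.2% and 44.9%). Since Saa3 served as a reference, the test says nothing against carried-over reads for Saa3 itself, the gene called in trauma. Blood in the sample is argued against by 4 haemoglobin genes, whose median log2 fold change was -0.474 (median of the single genes' SE 0.836). That holds for the group mean, since the erythroid list score was 2.02 in trauma 1 and -1.11 to -0.819 in the other trauma libraries. A trend with transcript length is argued against too, since its removal left the inflammatory median at 1.73. An inflammatory response to overload, the candidate explanation that the design gives, stays open as a hypothesis, as do differences between single mice.

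The oral epithelium list was lower in 62 of the 64 pairs of a library with and a library without a ligature. A smaller share of epithelium of the same makeup would lower all of its markers alike, provided that no other cells in the sample make them. That condition was not tested. In ligature against control 6 markers of the keratinised layers had a median log2 fold change of -7.29 and 7 basal and pan-epithelial markers one of -1.48. In ligature plus trauma against trauma the medians were -7.29 and -2.59. The ligature changed the difference between both sets by -4.07 on the log2 scale (two-sided exact permutation p = 0.000816 over 4900 relabellings within trauma status), from -1.21 ± 1.70 to -5.27 ± 1.31 (SD, n = 8 each). Both sets were chosen after the data were seen, so this p is no independent evidence. The keratinised-layer markers thus fell further than the others, but a smaller share of epithelium is not excluded. A length trend is argued against, as its removal left the list's median at -1.82. A smaller share, a change in the kind of epithelium sampled and a loss of keratinisation with the ligature may all play a part and cannot be parted here.

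Among 460 groups of 4 values of single genes, 41 held a library far from the other 3, where chance gives 23, and among 132 groups of list scores 8 did, where chance gives 6.6, because such a gap arises by chance in about 1 of 20 groups. No total count stood out. The gap to the nearest library is given as a share of the group's range. Ligature 2 stood out 11 times, control 1 7 times, trauma 3 6 times and trauma 1 5 times. Among list scores, ligature plus trauma 2 was high for resorption signals (0.895), ligature 2 for B cell (0.844) and for YAP/TAZ genes (0.881), trauma 4 for interferon-stimulated genes (0.885), trauma 1 for erythroid genes (0.907) and trauma 2 for salivary gland genes (0.834), while trauma 3 was low for Schwann cell genes (0.883) and ligature 4 for adipocyte genes (0.849).

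Among single genes, ligature 2 was high for Bdh2 (0.915) and S100a4 (0.897) and low for Sost (0.852), Mmp13 (0.895), Ptgs2 (0.951), Dlx6 (0.885), Nr4a1 (0.902), Fpr1 (0.855) and Tfrc (0.831). Control 1 was low for Mmp13 (0.939), Tcirg1 (0.895), Ocstamp (0.883), Col12a1 (0.83), Hapln1 (0.877), Sfrp4 (0.8293) and Cd68 (0.953). Trauma 3 was low for Ccl3 (0.884), Il1r2 (0.898), Ogn (0.952) and Gm34589 (0.958) and high for Sdf2l1 (0.833). Trauma 1 was low for S100a9 (0.844), Ckm (0.875) and Sdc1 (0.853) and was the single trauma library with counts of Adnp (1). Trauma 4 was low for Mcm5 (0.848) and high for Esam (0.947). In control, control 2 was high for Gm39321 (1) and Gm34589 (1), control 3 low for Sele (0.887) and high for Actg2 (1), and control 4 low for Ier3 (0.938). Ligature 3 was low for Irx2 (0.849) and ligature 4 high for Il1r2 (0.874). In ligature plus trauma, library 1 was high for Mmd2 (1), library 2 for Il6 (0.965), library 3 for Pgk1 (0.87) and Gm39321 (0.911) and low for Sost (0.91), and library 4 was low for Esam (0.942). Gm39321, Gm34589, Actg2 and Mmd2 were chosen after their values were seen.

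For 17 lists the effect of trauma differed with the ligature by the test of the difference itself (camera with a preset correlation, adjusted p), and for none of them with an estimated correlation. By fry only Wnt targets and regulators passed (fry adjusted p = 0.0227). On the log2 scale the effect of trauma was lower with the ligature for inflammatory genes (2.8e-12), cell cycle (1.38e-08), mature neutrophil (3.38e-07), oral epithelium (5.54e-05), hypoxia and glycolysis (0.000233), resorption signals (0.00359) and oxidative phosphorylation (0.0476). It was higher for Schwann cell and nerve (0.0002), osteoblast (0.000233), ligament fibroblast (0.000813), odontoblast, pulp and enamel organ (0.00885), immediate-early (0.026), Wnt targets and regulators (0.0296), erythroid (0.0315), mitochondrially encoded (0.0335), skeletal muscle (0.0384) and cartilage genes (0.0416). Of these, 8 lost their call when single libraries were left out, for which the highest value follows. Without ligature 2 cartilage was at 0.206 and oxidative phosphorylation at 0.953, without control 3 muscle at 0.901, without control 4 erythroid at 0.264, without ligature plus trauma 2 immediate-early at 0.403 and mitochondrial genes at 0.393, without ligature 1 Wnt at 0.0589, and without trauma 3 the odontoblast list at 0.0601. With the length trend removed cartilage (0.065), Wnt (0.065) and oxidative phosphorylation (0.279) lost their calls, and in the 13 libraries immediate-early (0.264), odontoblast (0.0632), cartilage (0.0609) and mitochondrial genes (0.459) did. Cartilage lost its call with the replicate block too (0.0751).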

How the results depend on the processing

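Tests chosen after the data were seen are the removal of the length trend, the length slope as a covariate and the fit of 13 libraries. The main counts were 2234, 1, 2609, 0, 1149 and 0 genes for ligature, trauma and both against control, both against ligature and against trauma, and the interaction. DESeq2 called more throughout: 3859, 127, 4470, 45, 2165 and 68. In simulated counts, which used edgeR's own spread and independent genes, 24.34% to 33.14% of its calls were false. Its share of false calls in the real counts was not measured. DESeq2 gave no adjusted p for Il6 or Krt1 with the ligature. The compared groups alone gave 1304 for ligature against control, but 2603 for both against control and 1068 against trauma. The cause of the drop in the first was not tested. The length slope as a covariate gave 1160 for both against control, 1724 against trauma and 1 for the interaction, and the 13 libraries gave 819, 447 and 2. Of the 2609 calls 753 were made again in the 13 libraries. With the length trend removed trauma against control had 2 genes. Leaving out each library in turn gave 1470 to 2041 genes for ligature, 0 to 3 for trauma and 1057 to 2881 for both against control, 584 to 1008 against trauma, 0 to 2 for the interaction and 0 against ligature. The lowest values came without ligature 1, control 4, ligature plus trauma 3 and again ligature plus trauma 3. The share of higher calls in both against trauma (464 of 1149) was 54.3% with voom and 64% in the 13 libraries. In both against control (1431 of 2609) it was 66.7% in the 13 libraries. The cause of these shifts was not tested.

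Size factors, no filter, a stricter filter and voom moved no count of genes by over 1.5 times. Saa3 was the gene of trauma against control in the other settings that called 1, but voom called Mmd2 (0.925 ± 0.39 CPM in control, 0 counts in trauma) in its place. Without control 2 Gm39321 and Gm34589 were added, without control 3 Actg2, without trauma 1 Bdkrb1 and Il6, and with the length trend removed Gm16157. In the interaction Saa3 passed with the covariate, in the 13 libraries (beside Exoc4) and without ligature plus trauma 3, and Gm39321 and Gm34589 without control 2. All of these but Saa3 and Il6 were chosen after their values were seen.

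The replicate number as a block gave 2082, 1, 2588, 0, 1032 and 0 genes. No clear pairing by number was seen, which does not exclude one. The deviations of 24 same-numbered pairs correlated at 0.0816 on average (-0.519 to 0.547, 13 pairs over 0.1) and those of 72 other pairs at -0.0267. Of 16 libraries 5 correlated best with their own number. Of 198 list results 190 were on the same side with the block, 4 gained and 4 lost the call. The lost ones were interferon-stimulated genes in ligature against control (0.0586), osteoblast (0.0564) and muscle genes (0.477) in both against ligature and cartilage in the interaction (0.0751). The gained ones were osteoclast genes in trauma against control (0.0456), immediate-early (0.0486) and cartilage genes (0.0486) in both against trauma and osteocyte genes in the interaction (0.035). Of 405 results of named genes 390 were on the same side, with 3 gained and 12 lost.

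List tests turned direction in 5 cases, given as -log10 of camera's unadjusted p with the sign of the direction. Mitochondrially encoded genes in both against control were at -0.853 with the length trend removed and -0.158 with the covariate. Mature neutrophil genes in both against ligature were at -1.81 in the 13 libraries, and muscle genes there at 2.38, where their median was -0.04. Muscle genes in both against ligature ranged from -8.71 without ligature 1 to 0.846 without ligature 2. The cause was not tested. Of 198 list results 86 were called by camera with the preset correlation. An estimated correlation took all 86 calls away, and fry took 51 and added 7. Fry left no list called in trauma against control (lowest fry adjusted p = 0.0525) or in both against ligature (lowest 0.464). In the interaction it called Wnt targets and regulators alone (0.0227). In ligature against control it took the calls of oral epithelium (0.101) and interferon-stimulated genes (0.138). In both against control it took those of interferon-stimulated (0.0577), ligament fibroblast (0.059), immediate-early (0.059), oral epithelium (0.0515) and mitochondrially encoded genes (0.244). In both against trauma it took those of inflammatory (0.384), neutrophil (0.126), muscle (0.271) and mitochondrially encoded genes (0.271). Other camera calls in these ligature comparisons stayed. No other call of a named gene or list turned direction in these settings. At the lowest total of 58458102 counts, depth limits genes near 0 such as Gpr22 and Irx2.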

Other observations

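The removal of the length trend, the length slope as a covariate and the fit of 13 libraries were tests chosen after the data were seen, whereas the lists were fixed before the data were examined and the genes are members with the lowest p.

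Macrophage genes changed in both directions with the ligature. In ligature against control 4 of 18 monocyte and macrophage genes rose and 3 fell, so that the list as a whole did not differ (median 0.29, camera adjusted p = 0.347). Cd68, a lysosomal protein gene of macrophages and osteoclasts, went from 72.7 ± 23.7 to 412 ± 122 CPM (mean ± SD, n = 4; log2 fold change 2.50 ± 0.33 SE, edgeR adjusted p = 0.000421), and Cd14, a receptor for bacterial lipopolysaccharide, rose by 2.50 ± 0.42. The haemoglobin scavenger receptor gene Cd163 went from 25.9 ± 3.37 to 3.65 ± 1.68 CPM (-2.82 ± 0.43, edgeR adjusted p = 0.000971), and the mannose receptor gene Mrc1, like Cd163 a marker of resident macrophages, fell by 1.72 ± 0.31 on the log2 scale. Ligature plus trauma against trauma gave Cd68 1.86 ± 0.32, Cd14 1.72 ± 0.41, Cd163 -2.57 ± 0.42 and Mrc1 -1.53 ± 0.30. In trauma alone Cd68 was at 91.5 ± 38.2 CPM and Cd163 at 18.5 ± 8.94 CPM.

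The remaining lists did not pass in ligature against control. Camera adjusted p was 0.218 for T and NK cell genes (1 of 17 higher, Trac at 1.55 ± 0.44), 0.539 for B cell genes (1 of 10 higher, median -0.05), 0.561 for plasma cell genes (1 of 7 higher, Sdc1) and 0.873 for antigen presentation (1 of 14 lower, Cd74 at -1.24 ± 0.22). It was 0.559 for marrow granulocyte precursors (1 of 13 lower, the lactoferrin gene Ltf at -3.77 ± 0.87, list median -2.97), 0.218 for osteocyte genes (1 of 12 higher and 1 lower), 0.553 for fibrillar collagen (1 of 22 higher, Col5a3 at 2.53 ± 0.43, and 2 lower, among them Col1a1 at -0.95 ± 0.25, although with the length trend removed the list passed upward at 0.0385 with a median of 0.26) and 0.937 for YAP/TAZ and stretch genes (2 of 20 higher, 1 lower). Immediate-early genes were at 0.937 (2 of 20 lower, among them Klf4), hypoxia and glycolysis at 0.559 (3 of 20 higher, among them Car9 at 3.24 ± 0.60) and endoplasmic reticulum stress at 0.0594 (3 of 16 higher, among them Sdf2l1 at 1.11 ± 0.22), which passed without control 1 (0.0387) or ligature 3 (0.045), with the covariate (0.0307) and in the 13 libraries (0.0254). Skeletal muscle was at 0.195 (none of 19) and passed upward without control 3 (0.00929), ligature 1 (0.00403) or ligature 4 (0.012). Erythroid genes were at 0.572 (1 of 13 higher, the transferrin receptor gene Tfrc), adipocyte genes at 0.221 (2 of 11 higher, 2 lower), salivary gland genes at 0.805 (1 of 7 lower) and mitochondrially encoded genes at 0.539 (none of 13). The B cell, plasma cell, YAP/TAZ, immediate-early, hypoxia and salivary gland lists had a median, mean and test that differed in sign.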
